A study of Mus musculus with 39 samples.

How the data were processed

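The series holds 39 samples of mouse testis RNA in 13 groups of 3. Testes were sampled in vivo at 7.5, 9.5, 11.5, 13.5, 14.5, 16.5 and 21.5 days post partum (dpp). Testes placed in organ culture at 7.5 dpp were sampled at the 6 later ages, after 2, 4, 6, 7, 9 and 14 days of culture. Per the labels' protocols, total RNA was extracted with Trizol, cleaned on FastPure columns with DNase treatment, checked on a Bioanalyser, and made into biotinylated cRNA using an Ambion kit for RNA amplification. It was hybridized to a 1-colour Illumina bead array.

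The deposited table of signals holds 1 intensity per probe and array for 45281 probes, not normalized between arrays, with no background subtraction evident in the values. Scanner software and its settings are not given in the sources used here. Beside each signal the deposited table holds a detection p-value, per the file headers, and its steps imply 936 negative control probes per array. A second table holds the authors' own values for 39 arrays on a log2 scale. Per the submitters' processing notes these were made with lumi, whose version and steps are not given. Every column of that table had the same median, 7.47. Where a deposited signal column carried the sample's name, the column also had the same rank order as those signals (rank correlation 1). Against the log2 of mid-range signal the slope of the authors' values was 0.963 on the first array, so the scale was treated as log2.

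One signal column is headed by an array code in place of a sample name. It and its detection column were not used here, because a column was matched to a sample only by name. No other column carries the name of replicate 1 of 13.5 dpp in vivo, which leaves 2 arrays in that group and 38 arrays in all, while the tests had been written for 39. That replicate entered only one alternative, which used the authors' values of all 39 arrays and was added after the data were examined.

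The signals were background corrected and quantile normalized on the log2 scale with neqc in limma 3.58.1 under R 4.3.3 (offset 16, controls inferred from the detection p-values). A probe was kept when its detection p was below 0.01 on at least 3 arrays, which 23665 probes met. Probe names came from the platform's table, in which 34885 probes had exactly 1 gene symbol, 18 had several and 10378 had none. Of the probes with 1 symbol, 34807 had a gene identifier in a reference gene table of the assembly GRCm38.p6, used for names only, and 0 symbols changed through it. The array files name no genome build, so no coordinates are given. Of the kept probes, 19924 had 1 symbol. Each gene was represented by its probe with the highest mean value over all arrays, which gave 12518 genes, 4961 of them with more than 1 kept probe. Probes without exactly 1 symbol were left out of the gene counts.

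The share of probes detected ran from 35.6% to 43.9% per array, the median signal from 71 to 102 and the mean signal from 368 to 789. The 14.5 dpp culture had the lowest mean signals, 368, 437 and 384, and detected shares of 38.6%, 39.7% and 38.0%, against 545 to 614 and 42.1% to 43.2% in the 21.5 dpp culture. The correlation between arrays of a group ran from 0.933 to 0.993. The number of arrays limits the precision of each value. The labels do not say whether the 3 samples of a group came from separate animals, so the p-values below measure only the spread between these samples.

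Groups were compared with limma (lmFit with 1 mean per group, eBayes with trend, 25 residual degrees of freedom), in which all 13 groups share the estimate of the spread. A gene was called when its Benjamini-Hochberg adjusted p was below 0.05 and its difference at least 2-fold (log2 difference of 1). The comparisons were culture against in vivo at each of 6 ages, 14.5 against 7.5 dpp and 21.5 against 14.5 dpp in vivo, culture day 2 and day 7 against the start at 7.5 dpp, culture day 14 against day 7, and the difference between culture and in vivo in the change from 14.5 to 21.5 dpp. Genes called in the same direction at all 6 ages were counted as well. Where all arrays of the lower group were below detection, the fold is given as a lower bound: each value of that group was raised to at least the lowest normalized signal of any detected probe on its array before the means were subtracted.

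Gene lists for 35 cell types and processes were fixed by hand from general knowledge: germ cell stages, somatic cells of the testis, blood and other cell types, immune responses, stroma, stress and metabolism. Each list with at least 5 measured members was tested against all other genes with camera from limma (preset inter-gene correlation 0.01), adjusted over the 34 lists tested within each comparison. The remaining list, epididymis epithelium, had 3 measured members of 18 and was not tested. For called lists the adjusted p from camera, or its range over several lists, is followed by the one obtained with an estimated correlation. Member counts are given over all genes tested and, where that differs, adjusted over the list alone. In each called list the median, the mean and the test had the same sign.

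Genes named in the text follow a fixed rule. It takes the 6 largest increases and 6 largest decreases per comparison among called genes whose groups did not overlap, up to 4 called members of each list in the direction of its test, and 30 marker genes, of which 22 were measured. Probes for Sycp3, Dmc1, Hsd3b6, Il6 and Mmp3 were too dim to keep, and Spp1 and Mki67 had no probe with a single symbol in the tables used. The members of the macrophage list and the genes called at all 6 ages that fall outside this rule were chosen after their values were seen. Comparisons, thresholds, lists, naming rule and all alternatives except those named as added were written before the data were examined.

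The alternatives were the authors' values, median centring in place of quantile normalization, no background correction (floor of 16), no filter, a stricter filter (13 arrays), the mean of a gene's probes, eBayes without trend, a replicate block, the compared groups alone, no minimum fold, an estimated correlation, fry from limma, and leaving out each array in turn. The alternatives without 4 or 6 doubted arrays were added after the data were examined. The 4 are replicate 2 of 9.5 dpp and replicate 1 of 11.5 dpp in vivo and replicate 3 of the 11.5 and of the 16.5 dpp cultures, and the 6 add replicate 3 of 13.5 dpp and replicate 2 of 16.5 dpp in vivo. All were doubted for their correlations with other arrays, but best matches alone did not decide the choice. Replicate 1 of 11.5 dpp in vivo matched its own group best (0.970). Some arrays that matched another group best were kept, such as replicate 3 of the 9.5 dpp culture (0.986). In vivo, replicate 2 of 13.5 dpp correlated best with replicate 2 of 16.5 dpp (0.987) and replicate 3 of 13.5 dpp with replicate 1 of 16.5 dpp (0.985). A block for slide or scan was not run, since the tables give neither. The labels use replicate numbers 1 to 3 in every group without saying what they share. Deviations from the group means of same-numbered arrays correlated in each of the 3 pairs only for culture day 14 against day 7 (r from 0.35 to 0.46). The values given for that comparison come from the fit without pairing. The pairing entered only as an alternative, with a replicate block over all groups or in these 2 groups alone.

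The scripts were tested on simulated data with 200 changed genes among the 12518, made with the spread of these arrays. For culture against in vivo at 21.5 dpp, 83.6% of genes changed by a log2 difference of 1.5, 94% of those changed by 2 and 100% of those changed by 3 were recovered, with 2 false calls. For the difference between the changes from 14.5 to 21.5 dpp these shares were 67.2%, 89.6% and 97%. The simulated spread was independent and normal around 1 mean per gene, and the values were not normalized again. They held no deviations shared by replicates, no arrays resembling another group and no shift of all genes. These shares therefore need not hold for the real arrays. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.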

Results

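Gene expression was measured on bead arrays in mouse testes that developed in vivo and in testes kept in organ culture from 7.5 dpp, a method in which a piece of immature testis is cultured so that its germ cells can enter and pass through meiosis. The 38 arrays used covered 7 ages in vivo and 6 culture times, with 3 arrays per group except 13.5 dpp in vivo, which had 2. Values are means of normalized log2 signal ± SD, differences are log2 differences ± SE, and n = 3 per group unless stated otherwise. Between 35.6% and 43.9% of probes were detected per array.

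**Figure D1:**
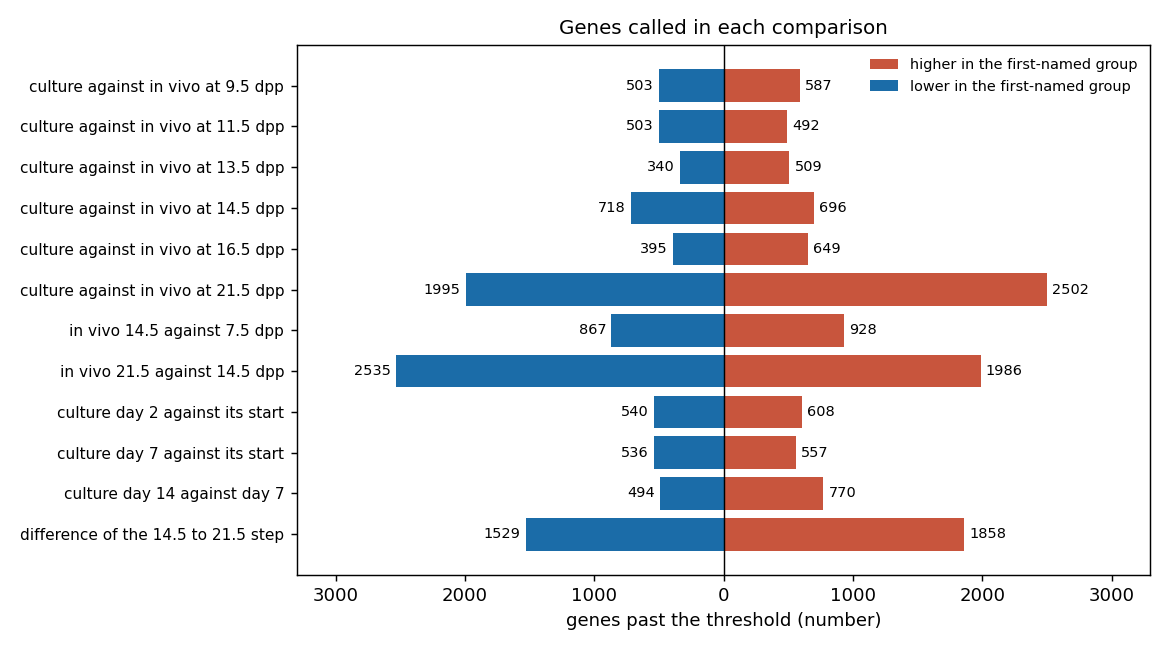
Number of genes (horizontal axis) called higher (right) or lower (left) in the first-named group of each of the 12 comparisons. The largest counts were those that involved 21.5 dpp in vivo, with 2502 genes higher and 1995 lower in culture at that age.

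Development in vivo from 7.5 to 14.5 dpp, the reference for what a cultured testis would have to match, included a rise of the genes of meiosis. Meiob, which acts in meiotic recombination, was below detection at 7.5 dpp and at least 66-fold higher at 14.5 dpp (difference 6.56 ± 0.50, limma adjusted p = 3.77e-10). Ldhc, the lactate dehydrogenase of spermatocytes, rose by 6.69 ± 1.34 (limma adjusted p = 0.000328), and Piwil1, a piRNA-binding protein of pachytene cells, rose by 4.88 ± 1.12 (limma adjusted p = 0.00125). Among Sertoli cell genes, Rhox5 rose by 3.49 ± 0.47 (limma adjusted p = 2.04e-06) while Amh, the hormone of immature Sertoli cells, fell by 2.80 ± 0.49 (limma adjusted p = 6.73e-05). Of the early meiotic prophase list 21 of 28 measured members rose and none fell (mean 2.15, camera adjusted p = 2.4e-19, 0.0422 with an estimated correlation). Of the pachytene list 19 of 27 rose (mean 2.65, camera adjusted p = 4e-13, 0.13 with an estimated correlation). The piRNA pathway list (12 of 18 rose) and the axoneme list of flagella and cilia (17 of 30 rose) were higher as well (camera adjusted p = 1.22e-08 and 4.65e-07, 0.13 and 0.308 with an estimated correlation).

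Stromal genes moved the other way over the same week in vivo. Inhba fell by 3.31 ± 0.28, the matrix protease Mmp2 fell by 2.90 and Col1a1 fell by 1.49 ± 0.36. Of the fibrillar collagen and matrix list 16 of 21 members fell (camera adjusted p = 3.12e-09, 0.0692 with an estimated correlation), and of the interstitial progenitor list 11 of 15 fell (camera adjusted p = 7.9e-08, 0.0422 with an estimated correlation). The undifferentiated spermatogonia list was lower, with 7 of 23 members down, among them Lhx1 (at least 3.39-fold), and 2 up (camera adjusted p = 0.00209, 0.112 with an estimated correlation). The lists of peritubular cells, endothelium, wound and matrix remodelling, and cholesterol synthesis were also lower (camera adjusted p from 0.00119 to 0.0188, from 0.0939 to 0.565 with an estimated correlation). In all, 928 genes were higher and 867 lower at 14.5 than at 7.5 dpp in vivo.

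From 14.5 to 21.5 dpp in vivo the genes of spermatids rose. The protamine gene Prm1 rose from 4.48 ± 0.01, below detection, to 11.25 ± 1.40, at least 48.5-fold (limma adjusted p = 1.03e-17). The acrosomal gene Acrv1 rose at least 68.8-fold (7.33 ± 0.16, limma adjusted p = 8.35e-27), and Pgk2, the glycolytic enzyme of late spermatocytes and spermatids, rose by 6.15 ± 0.64 (limma adjusted p = 1.37e-09). All 20 measured genes of elongating spermatids rose (mean 5.21, camera adjusted p = 2.55e-26, 0.00337 with an estimated correlation), as did 28 of 29 of round spermatids (mean 4.26, camera adjusted p = 1.42e-25, 0.00054 with an estimated correlation). The pachytene list (18 of 27 rose) and the axoneme list (25 of 30 rose) were higher too (camera adjusted p = 9.6e-06 and 1.71e-10, 0.451 and 0.288 with an estimated correlation).

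Sertoli, stromal and spermatogonial genes fell over the same step in vivo. Dlk1 fell by 3.43 ± 0.31, Amh fell by 2.12 ± 0.49, Sox9 fell by 2.00 and Acta2 fell by 1.38 ± 0.14, while the steroidogenic gene Cyp17a1 rose by 3.87 ± 0.87 (limma adjusted p = 0.000337). Lower lists were undifferentiated spermatogonia (10 of 23 fell), differentiating spermatogonia (10 of 13), Sertoli cells (11 of 24), interstitial progenitors (9 of 15), peritubular cells (8 of 13, 1 rose), fibrillar collagen (15 of 21, 16 adjusted over the list alone) and p53 and apoptosis (7 of 17). Their camera adjusted p-values ran from 0.00631 to 0.04, and from 0.288 to 0.485 with an estimated correlation. In total 1986 genes were higher and 2535 lower. The median of all genes shifted by -0.34, against which the list falls are to be read. The share higher was 43.9%, and 59.3% with the authors' values.

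Organ culture itself was examined first against its own starting material. After 2 days of culture the acute phase gene Saa3 rose from 4.77 ± 0.26, below detection, to 14.05 ± 0.13, at least 338-fold (limma adjusted p = 3.78e-11). Serpina3n rose at least 140-fold, the chemokine Cxcl1 by 5.90, the interferon-induced gene Ifit3 by 5.03, and the major histocompatibility gene H2-Ab1 at least 12.8-fold. Of the cytokine and chemokine list 19 of 22 members rose (mean 3.05, camera adjusted p = 4.17e-26, 0.0033 with an estimated correlation). Of the interferon response list 19 of 25 rose (mean 2.15, camera adjusted p = 1.77e-22, 0.00835 with an estimated correlation), and of antigen presentation genes 16 of 19 (mean 2.53, camera adjusted p = 6.77e-18, 0.0131 with an estimated correlation). Complement genes rose in 5 of 12 cases, 6 adjusted over the list alone (camera adjusted p = 0.000214, 0.0375 with an estimated correlation).

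Early meiotic genes rose during these first 2 days as well, and cell cycle genes fell. Meiob rose at least 11.4-fold and Msh5 at least 3.81-fold, with 15 of 28 early meiotic genes higher (camera adjusted p = 4.35e-07, 0.205 with an estimated correlation). The steroidogenic gene Cyp17a1 fell by 5.74 ± 0.87 (limma adjusted p = 1.56e-05), Insl3 fell by 2.40 and Amh fell by 3.85 ± 0.49. Of the cell cycle list 5 of 24 members fell, among them Nusap1 and Cdk1 (camera adjusted p = 3.15e-06, 0.0203 with an estimated correlation). Of the undifferentiated spermatogonia list 8 of 23 fell and 2 rose (camera adjusted p = 0.00126, 0.0743 with an estimated correlation). The endothelium, peritubular and oxidative stress lists were called with 5, 1 and 2 members past the threshold (camera adjusted p from 0.000847 to 0.0124, from 0.177 to 0.379 with an estimated correlation). The totals were 608 genes higher and 540 lower than at the start.

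At culture day 7 cytokine and meiotic genes were above the start. Saa3 was at least 22-fold and Gpnmb, a glycoprotein of lipid-laden macrophages, at least 44.9-fold above the start. Meiob was at least 20.6-fold higher (limma adjusted p = 3.32e-08) and Rhox5 rose by 3.34 ± 0.47 (limma adjusted p = 6.33e-06), while Piwil1 did not pass (2.69 ± 1.12, limma adjusted p = 0.0768). Early meiotic genes were higher in 15 of 28 cases (camera adjusted p = 7.53e-10, 0.215 with an estimated correlation) and pachytene genes in 9 of 27, 14 adjusted over the list alone (camera adjusted p = 3.64e-05, 0.481 with an estimated correlation). The haemoglobin gene Hba-a1 fell by 7.59 ± 0.73 (limma adjusted p = 1.15e-08) and 5 of 7 erythrocyte genes fell (camera adjusted p = 2.23e-05, 0.157 with an estimated correlation). Hba-a1, Hbb-bs and Hbb-bt have near-identical copies, and which copy their probes measured is uncertain. Cytokine genes were higher in 9 of 22 cases (mean 1.26, camera adjusted p = 1.1e-05, 0.306 with an estimated correlation), while the interferon response list was not called (6 of 25 higher, 1 lower, camera adjusted p = 0.209, 0.851 with an estimated correlation). The lists of antigen presentation (5 of 19, 6 adjusted over the list alone), complement (3 of 12) and endothelium (8 of 21) were higher, and those of undifferentiated spermatogonia, peritubular cells, collagen and cell cycle lower with 2 or 3 members each (camera adjusted p from 0.00123 to 0.0449, from 0.215 to 0.481 with an estimated correlation). Day 7 counted 557 genes higher and 536 lower than the start, or 51% higher, against 13% with median centring, where the median of all genes was -0.35. Median centring took the list mean of endothelium from 0.69 to 0.27, of complement from 0.64 to 0.25 and of antigen presentation from 0.81 to 0.46. It enlarged the falls of the lower lists, that of cell cycle from -0.45 to -0.89.

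Between culture day 7 and day 14 genes of late spermatocytes rose. Pgk2 rose from below detection at least 14.1-fold (4.99 ± 0.64, limma adjusted p = 2.74e-06), the meiotic cyclin Ccna1 at least 8.76-fold, and Pabpc2 at least 51.6-fold. The pachytene list rose in 16 of 27 members, 17 adjusted over the list alone (mean 1.76, camera adjusted p = 1.73e-08, 0.344 with an estimated correlation), and the axoneme list in 17 of 30 (camera adjusted p = 6.87e-09, 0.291 with an estimated correlation). Of round spermatid genes 8 of 29 rose, among them Zpbp2 at least 6.63-fold and Acrbp by 3.28 (camera adjusted p = 8.41e-07, 0.157 with an estimated correlation), while Acrv1 was undetected at day 7 and detected on 1 of 3 arrays at day 14, and Prm1 was below detection at both times. The piRNA list rose in 5 of 18 members, 6 adjusted over the list alone (camera adjusted p = 0.00149, 0.501 with an estimated correlation).

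Somatic signals also shifted in the second week of culture. The macrophage gene Adgre1 rose at least 3.52-fold (limma adjusted p = 8.9e-05), and 13 of 25 macrophage genes rose, 16 adjusted over the list alone (camera adjusted p = 1.94e-06, 0.454 with an estimated correlation). The endothelial genes Gpihbp1, Cldn5 and Cdh5 fell by 3.13 ± 0.40, by 2.49 and by 2.32 (log2 differences -3.13, -2.49 and -2.32), and 13 of 21 endothelial genes fell (mean -1.43, camera adjusted p = 4.33e-12, 0.0972 with an estimated correlation). The lists of interstitial progenitors (6 of 15), collagen (6 of 21), wound and matrix remodelling (6 of 16), undifferentiated spermatogonia (8 of 23, 1 rose) and differentiating spermatogonia (2 of 13) fell (camera adjusted p from 0.000804 to 0.0143, from 0.148 to 0.378 with an estimated correlation). These 5 falls depended on the scaling. With median centring the list means went from -0.57 to 0.01 for differentiating spermatogonia, from -0.52 to 0.00 for undifferentiated spermatogonia, from -0.64 to -0.11 for collagen, from -0.75 to -0.20 for interstitial progenitors and from -0.83 to -0.32 for wound remodelling, and that of endothelium from -1.43 to -0.85. There were 770 genes higher and 494 lower at day 14 than at day 7, or 60.9% higher, against 97.3% with median centring, where the median of all genes was 0.46, and 79.9% with the authors' values. The day 7 arrays had the lowest mean signals of all groups (368 to 437, against 545 to 614 at day 14).

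**Figure D2:**
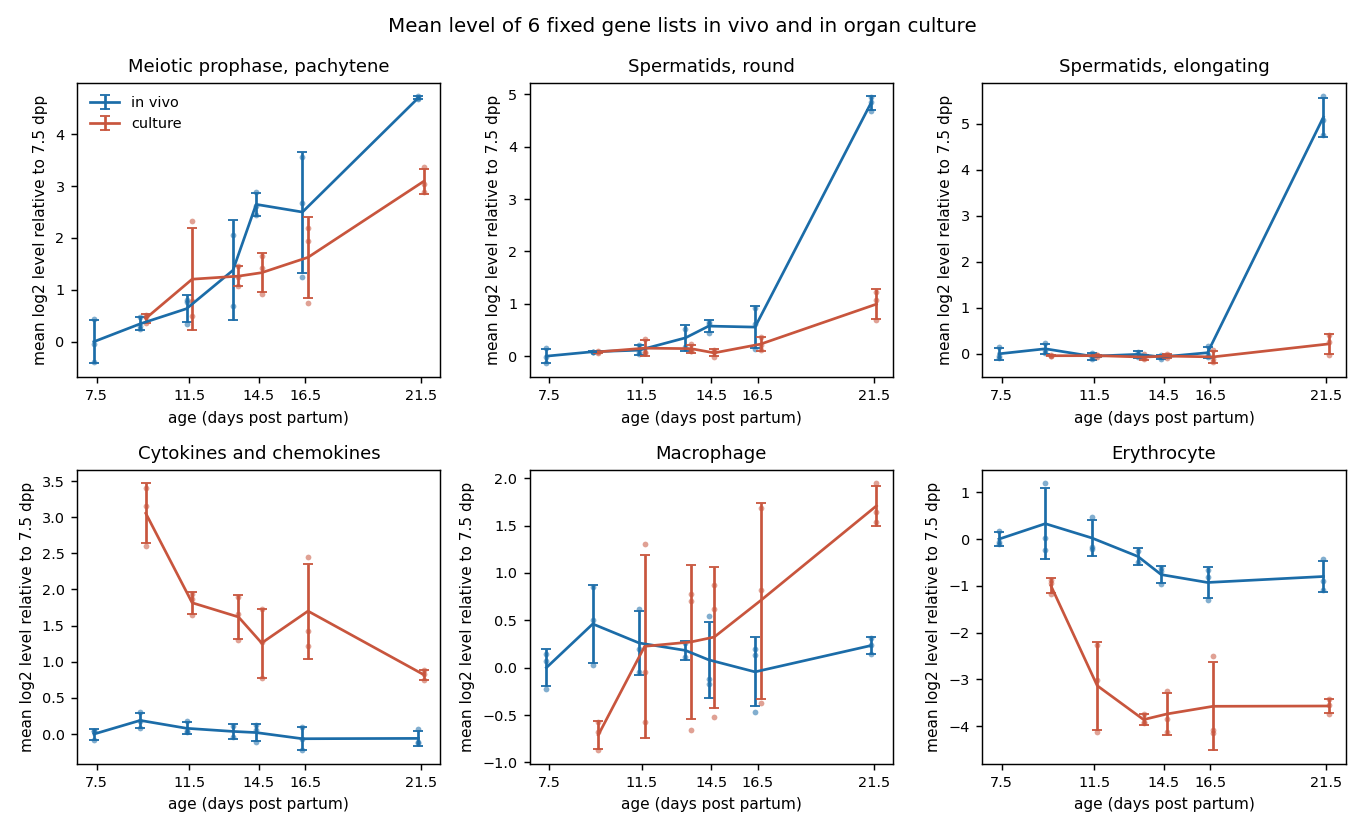
Mean log2 level of 6 gene lists relative to 7.5 dpp in vivo (vertical axis) against age in days post partum, in vivo and in culture. Points are arrays and lines join group means with bars of 1 SD. At 21.5 dpp the elongating spermatid list stood at 5.14 ± 0.42 in vivo and 0.22 ± 0.22 in culture.

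At 9.5 dpp, after 2 days, cultured testes differed from testes of the same age in vivo in inflammatory genes. Saa3 was at least 339-fold higher (9.05 ± 0.67, limma adjusted p = 9.85e-11), and Serpina3n was higher by 7.45 ± 0.50 (limma adjusted p = 1.06e-11). The chemokine Ccl2, below detection in vivo, was at least 6.08-fold higher (limma adjusted p = 2.06e-06). Cytokine and chemokine genes were higher in 19 of 22 cases (mean 2.86, camera adjusted p = 4.8e-24, 0.00538 with an estimated correlation). Interferon response genes were higher in 20 of 25 (mean 2.11, camera adjusted p = 2.15e-22, 0.00852 with an estimated correlation) and antigen presentation genes in 12 of 19, 13 adjusted over the list alone (mean 1.77, camera adjusted p = 1.38e-09, 0.0929 with an estimated correlation). Complement (7 of 12, 1 lower) and wound remodelling genes (6 of 16, with Tnc at least 8.42-fold and Timp1 by 3.12) were higher, each with camera adjusted p = 0.000102, 0.0302 with an estimated correlation. Endothelial genes were higher in 7 of 21 cases, Pecam1 by 1.55 ± 0.31 (camera adjusted p = 0.000793, 0.407 with an estimated correlation).

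Macrophage genes and single endocrine genes were lower at this age. The complement component C1qb, made by macrophages, was at least 11.8-fold lower, F13a1 at least 8.22-fold and Adgre1 at least 1.35-fold, and 14 of 25 macrophage genes were lower while 2, Cd14 and Gpnmb, were higher (mean -1.17, camera adjusted p = 0.000793, 0.557 with an estimated correlation). Cyp17a1 had a level of 6.23 ± 0.46 in culture and 11.18 ± 1.03 in vivo (limma adjusted p = 0.000131). Insl3 was lower by -2.41 ± 0.34 (limma adjusted p = 5.91e-06) and Amh by -3.57 ± 0.49 (limma adjusted p = 4.8e-06). The list of Leydig cells and steroidogenesis as a whole was called in no comparison, its lowest camera adjusted p being 0.0578 at this age with 2 of 13 members higher and 3 lower (0.552 is its lowest with an estimated correlation). Germ cell markers such as Kit (0.70, limma adjusted p = 0.16), Zbtb16 and Piwil1 did not pass, while Stra8, the retinoic acid-induced gene of premeiotic cells, was lower by -1.03 ± 0.34 (limma adjusted p = 0.0261). Erythrocyte genes (4 of 7, 5 adjusted over the list alone), cell cycle genes (5 of 24), oxidative phosphorylation genes (6 of 36) and peritubular genes (2 of 13) were lower, and hypoxia (3 of 20) and oxidative stress genes (2 of 21) higher (camera adjusted p from 0.00347 to 0.0483, from 0.205 to 0.557 with an estimated correlation). The totals were 587 genes higher and 503 lower, a share of 53.9% higher that was 67.5% with median centring and 66.9% with the authors' values. Leaving out replicate 1 of 9.5 dpp in vivo raised the count to 1482. Replicate 2 of that group had the lowest detected share, 35.6%, and without it 861 genes were called. Of the macrophage list 9 members were then lower in place of 14 (camera adjusted p = 0.0123, 0.701 with an estimated correlation). The erythrocyte, hypoxia and oxidative phosphorylation lists lost their calls once it and 3 other doubted arrays were left out.

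At 11.5 dpp inflammatory genes were higher and haemoglobin genes lower in culture. Saa3 was at least 59.3-fold higher in culture (limma adjusted p = 6.5e-08) and Ccl2 at least 1.92-fold. Cytokine genes were higher in 14 of 22 cases, 15 adjusted over the list alone (mean 1.74, camera adjusted p = 3.01e-12, 0.0687 with an estimated correlation). Interferon genes were higher in 10 of 25, 11 adjusted over the list alone (camera adjusted p = 1.07e-07, 0.185 with an estimated correlation). Endothelial genes were higher in 9 of 21, Pecam1 by 2.01 ± 0.31 (camera adjusted p = 1.07e-07, 0.137 with an estimated correlation). Hba-a1 was lower by -6.32 ± 0.73 (limma adjusted p = 4.88e-07) and 4 of 7 erythrocyte genes were lower (camera adjusted p = 0.000144, 0.115 with an estimated correlation). Insl3 (-3.67 ± 0.34, limma adjusted p = 1.11e-08), Cyp17a1 (-5.66 ± 0.87, limma adjusted p = 3.98e-05), Rhox5 (-2.22 ± 0.47, limma adjusted p = 0.00122) and Stra8 (-1.11 ± 0.34, limma adjusted p = 0.0187), were lower. Differentiating spermatogonia (2 of 13 lower, 3 adjusted over the list alone) and retinoid genes (3 of 16 lower, among them Rarg at least 2.81-fold, 1 higher) were lower, and wound remodelling (6 of 16), antigen presentation (6 of 19, 7 adjusted over the list alone) and complement genes (4 of 12, 1 lower) higher (camera adjusted p from 8.01e-05 to 0.0437, from 0.0687 to 0.637 with an estimated correlation). Cell cycle (1 of 24) and oxidative phosphorylation genes (5 of 36) were lower (camera adjusted p = 0.0468 and 0.011, 0.439 and 0.637 with an estimated correlation). There were 492 genes higher and 503 lower, and with the authors' values 61.4% of the called genes were higher. The array labelled replicate 3 of the 11.5 dpp culture resembled the 16.5 dpp culture more than its own group. Without it and 3 other doubted arrays 900 genes were called and the complement, oxidative phosphorylation and retinoid lists were not.

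At 13.5 dpp, with 2 arrays in vivo, endothelial genes were higher in culture. Gpihbp1, the lipase-binding protein of capillaries, was higher by 4.71 ± 0.45 (limma adjusted p = 9.52e-09), and 12 of 21 endothelial genes were higher, 13 adjusted over the list alone (mean 1.19, camera adjusted p = 5.86e-12, 0.0508 with an estimated correlation). Saa3 was at least 39.8-fold and Gpnmb at least 41.7-fold higher, with cytokine genes up in 11 of 22 cases, 13 adjusted over the list alone (camera adjusted p = 4.08e-11, 0.0727 with an estimated correlation). Wound remodelling genes were up in 7 of 16 (camera adjusted p = 6.89e-07, 0.0146 with an estimated correlation). Hba-a1 was lower by -7.49 ± 0.82 (limma adjusted p = 1.12e-07) and Insl3 by -3.23, and 4 of 7 erythrocyte genes were lower (camera adjusted p = 0.00101, 0.137 with an estimated correlation). Early meiotic genes were lower in 3 of 28 cases, 4 adjusted over the list alone, among them Syce2 (-1.48 ± 0.37, limma adjusted p = 0.00687, camera adjusted p = 0.00355, 0.627 with an estimated correlation). Interferon (5 of 25), complement (2 of 12, 1 lower) and antigen presentation genes (3 of 19, 5 adjusted over the list alone) were higher (camera adjusted p from 0.000316 to 0.0445, from 0.137 to 0.684 with an estimated correlation). The counts were 509 genes higher and 340 lower, or 60% higher, against 23.5% with median centring, which shifted the median of all genes to -0.35, and 75.7% with the authors' values. They rested on each in vivo array: 531 genes were called without replicate 2 and 552 without replicate 3, a lone array then being assumed to vary like the other groups. Both in vivo arrays correlated best with an array of 16.5 dpp in vivo (0.987 and 0.985), and Piwil1 spread widely between them (9.68 ± 3.05). With 6 doubted arrays left out the early meiotic, antigen presentation and complement lists lost their calls.

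At 14.5 dpp meiotic genes were lower in culture. Spo11, which makes the breaks that start recombination, was lower by -2.07 ± 0.47 (limma adjusted p = 0.00162), Ddx4, the germ cell helicase, by -2.55 ± 0.50 (limma adjusted p = 0.000422), and Clgn, a chaperone of spermatocytes, by -2.50 ± 0.57 (limma adjusted p = 0.00175). Early meiotic genes were lower in 12 of 28 cases (mean -0.85, camera adjusted p = 9.35e-06, 0.256 with an estimated correlation) and pachytene genes in 10 of 27, 11 adjusted over the list alone (mean -1.32, camera adjusted p = 4.24e-05, 0.47 with an estimated correlation). The piRNA list (11 of 18 lower), the axoneme list (13 of 30, 15 adjusted over the list alone) and the round spermatid list (7 of 29 lower, 1 higher) were lower as well (camera adjusted p from 1.9e-05 to 0.0189, from 0.256 to 0.47 with an estimated correlation).

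Stromal and vascular genes were higher in culture at 14.5 dpp. Gpnmb was at least 44.9-fold higher (limma adjusted p = 1.56e-09), Gpihbp1 at least 31.3-fold, and Mmp2 was higher by 2.44. The cholesterol synthesis gene Fdps was higher by 1.34 ± 0.14 (limma adjusted p = 6.18e-08) and Amh by 1.34 ± 0.49 (limma adjusted p = 0.0391), but the Sertoli cell list was not called (3 of 24 members higher, 1 lower). Endothelial genes were higher in 11 of 21 cases (camera adjusted p = 3.21e-07, 0.152 with an estimated correlation). Collagen and matrix genes were higher in 10 of 21, with 1 lower (camera adjusted p = 7.11e-05, 0.224 with an estimated correlation), and interstitial progenitor genes in 5 of 15 (camera adjusted p = 7.19e-05, 0.152 with an estimated correlation). Higher too were cytokine (10 of 22), interferon (8 of 25), antigen presentation (4 of 19, 5 adjusted over the list alone), complement (5 of 12), wound remodelling (8 of 16, 1 lower) and cholesterol synthesis genes (4 of 18), with camera adjusted p from 1.85e-05 to 0.0245, from 0.0937 to 0.574 with an estimated correlation. Erythrocyte genes were lower in 3 of 7 (camera adjusted p = 0.000756, 0.165 with an estimated correlation). F13a1 was at least 10.1-fold lower and Insl3 lower by -2.26, while Cyp17a1 did not pass (-1.76 ± 0.87, limma adjusted p = 0.13), its level in vivo then ranging widely (8.84 ± 2.25). In total 696 genes were higher and 718 lower, or 49.2% higher, against 14% with median centring, where the median of all genes was -0.27. The means of the higher lists shrank with median centring. Interferon went from 0.53 to 0.27, antigen presentation from 0.53 to 0.21, complement from 0.99 to 0.62 and cholesterol synthesis from 0.51 to 0.15. Those of the lower lists moved further down, early meiosis from -0.85 to -1.23. The 14.5 dpp culture arrays had lower mean signals (368 to 437) than those in vivo (468 to 554), a difference between whole arrays that runs with both sets of results at this age.

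At 16.5 dpp vascular, matrix and cytokine genes were higher in culture. Pecam1 was higher by 2.62 ± 0.31 (limma adjusted p = 4.63e-07), Mmp2 by 3.56 ± 0.38, and Gpnmb at least 64.9-fold. Endothelial genes were higher in 12 of 21 cases (mean 1.51, camera adjusted p = 9.87e-14, 0.0282 with an estimated correlation). Wound remodelling genes were higher in 9 of 16, 10 adjusted over the list alone (camera adjusted p = 7.22e-08, 0.00687 with an estimated correlation), and cytokine genes in 14 of 22 (mean 1.77, camera adjusted p = 3.42e-12, 0.0452 with an estimated correlation). Complement genes were higher in 6 of 12, 1 lower (camera adjusted p = 0.000168, 0.0452 with an estimated correlation). Sycp1, a protein of the synaptonemal complex that holds paired chromosomes, was lower by -1.51 ± 0.30 (limma adjusted p = 0.00062), Insl3 by -3.29 ± 0.34 (limma adjusted p = 2.63e-08), and Hba-a1 by -5.92 ± 0.73 (limma adjusted p = 7.52e-07). Lower lists were early meiosis (4 of 28), pachytene (2 of 27), piRNA (4 of 18), erythrocyte (3 of 7), oxidative phosphorylation (3 of 36) and axoneme, of which no single member passed (camera adjusted p from 0.000155 to 0.0107, from 0.241 to 0.518 with an estimated correlation). Interstitial progenitor (7 of 15), interferon (9 of 25, 10 adjusted over the list alone), antigen presentation (4 of 19, 5 adjusted over the list alone), collagen (6 of 21), oxidative stress (3 of 21) and p53 genes (2 of 17, 1 lower) were higher (camera adjusted p from 9.07e-06 to 0.0462, from 0.0552 to 0.518 with an estimated correlation). The totals were 649 genes higher and 395 lower, or 62.2% higher, against 48.6% with median centring and 74.7% with the authors' values. The array labelled replicate 3 of this culture resembled the 11.5 dpp culture more than its own group. Without it and 3 other doubted arrays 928 genes were called, the axoneme, antigen presentation, oxidative stress and p53 lists lost their calls and the macrophage list was higher (7 of 25 members, 1 lower, camera adjusted p = 4e-05, 0.562 with an estimated correlation). Without replicate 2 of 16.5 dpp in vivo, 1650 genes were called. No array of 16.5 dpp in vivo correlated best with its own group, 2 matching 13.5 dpp and 1 matching 14.5 dpp, and Piwil1 spread widely there (12.39 ± 2.41).

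At 21.5 dpp, after 14 days, spermatid transcripts were lower in the cultured testes. Prm1 was below detection in culture (4.58 ± 0.12) against 11.25 ± 1.40 in vivo, at least 58.2-fold lower (limma adjusted p = 1.65e-17), and Tnp1, the transition protein that precedes protamines, was at least 24.2-fold lower (limma adjusted p = 1.88e-11). Acrv1 was at 5.11 ± 0.51 against 11.75 ± 0.19 (limma adjusted p = 1.05e-25), detected on 1 of 3 cultured arrays. All 20 elongating spermatid genes were lower (mean -4.92, camera adjusted p = 7.27e-26, 0.00372 with an estimated correlation), and 28 of 29 round spermatid genes (mean -3.84, camera adjusted p = 2e-23, 0.000986 with an estimated correlation). Pachytene genes were lower in 17 of 27 cases (mean -1.61, camera adjusted p = 0.00011, 0.438 with an estimated correlation), with Pgk2 lower by -3.22 ± 0.64 (limma adjusted p = 6.87e-05), and axoneme genes in 24 of 30 (camera adjusted p = 6.09e-09, 0.257 with an estimated correlation). Piwil1 did not pass (-1.06 ± 1.12, limma adjusted p = 0.427), nor did Stra8 and Zbtb16, and Kit was higher in culture by 1.26 ± 0.36 (limma adjusted p = 0.00313).

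Sertoli and interstitial progenitor genes were higher in culture at this age. Amh stood at 8.03 ± 0.41 in culture and 5.39 ± 0.05 in vivo (limma adjusted p = 3.1e-05). Sox9 was higher by 1.74 ± 0.28 (limma adjusted p = 3.54e-06), and 13 of 24 Sertoli cell genes were higher (mean 1.09, camera adjusted p = 0.00125, 0.216 with an estimated correlation). Dlk1 was higher by 2.91 ± 0.31 (limma adjusted p = 2.84e-09) with 11 of 15 interstitial progenitor genes (mean 1.65, camera adjusted p = 0.0012, 0.216 with an estimated correlation), and Acta2 by 1.05 ± 0.14 (limma adjusted p = 2.49e-07). Lyz2 was higher by 4.00 ± 0.89 (limma adjusted p = 0.000286), though its separation from the near copy Lyz1 is uncertain. In all 15 of 25 macrophage genes were higher and 2 lower, although the list was not called. The steroidogenic gene Cyp17a1 was lower by -5.11 ± 0.87 (limma adjusted p = 1.01e-05) and Insl3 by -2.67 ± 0.34. Collagen (15 of 21, 1 lower), hypoxia (8 of 20, 1 lower), p53 (9 of 17) and cholesterol synthesis genes (8 of 18) were higher and erythrocyte genes (4 of 7) lower (camera adjusted p from 0.00169 to 0.0414, from 0.216 to 0.512 with an estimated correlation). Without 4 doubted arrays of other groups the hypoxia list lost its call and the piRNA list was lower in 7 of 18 members (camera adjusted p = 0.0314, 0.604 with an estimated correlation). In all, 2502 genes were higher and 1995 lower, with a median shift of all genes of 0.25. The share higher was 55.6%, and 43.4% with the authors' values.

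A set of 92 genes was called in the same direction at all 6 ages, 76 higher and 16 lower in culture, where independent lists of these sizes would share 7e-04. The set held 27 genes with the authors' values, 50 with the compared groups only and 52 without background correction. Leaving out single arrays gave from 66 to 96 genes. The higher genes included Saa3 (at least 11.6-fold at 21.5 dpp and 339-fold at 9.5 dpp), Gpnmb, Serpina3n and Car12. They also included Igfbp3 (3.12 to 4.30), Mmp2 (1.36 to 3.56) and B2m (1.58 to 1.99), given as ranges of fitted log2 differences over the ages. Lower at every age were Hba-a1, F13a1, Cbr2, Cd209f, Vsig4, Folr2 and Insl3. No member of the macrophage list was lower at all 6 ages, and its members Cd14 and Gpnmb were higher at all 6. This holds only for the list fixed by hand, to which F13a1, Cbr2, Cd209f, Vsig4 and Folr2 do not belong. It does not show that no macrophage gene was lower throughout. The level of Insl3 in culture never exceeded 9.58 ± 0.10 while in vivo it was at least 11.03 ± 0.60. Across the ages 6161 genes were called at 1 or more, and 222 were higher at some ages and lower at others.

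**Figure D3:**
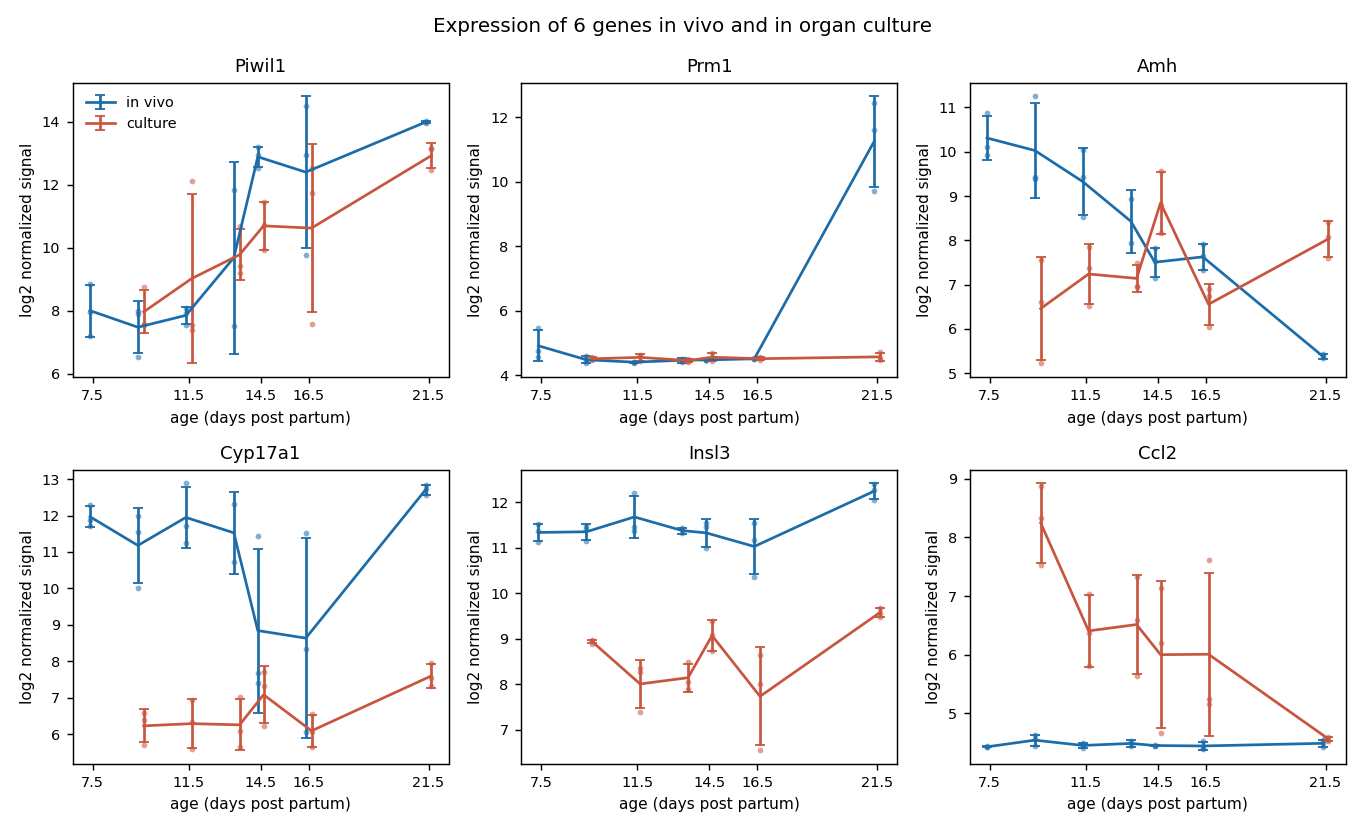
Normalized log2 signal (vertical axis) of 6 marker genes against age in days post partum, in vivo and in culture. Points are arrays and lines join group means with bars of 1 SD. Insl3 in culture stayed at or below 9.58 ± 0.10, and Prm1 was detected only at 21.5 dpp in vivo.

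The change from 14.5 to 21.5 dpp differed between culture and in vivo in 3387 genes. The change in culture minus that in vivo was positive in 1858 and negative in 1529. A positive value can be a larger rise or a smaller fall in culture, and a negative value the reverse. Spermatid genes were among the 3387. The in vivo rises of Prm1 (at least 48.5-fold), Acrv1 (at least 68.8-fold) and Tnp1 (at least 20.1-fold) were larger than those in culture (limma adjusted p = 1.64e-13, 3.33e-21 and 4.66e-08). In culture Prm1 and Tnp1 were undetected on all arrays at both ages and Acrv1 on all but 1, so that no exact size of these differences is given. All 20 elongating spermatid genes (mean -4.94, camera adjusted p = 6.83e-34, 0.000724 with an estimated correlation) and 23 of 29 round spermatid genes, 24 adjusted over the list alone (mean -3.33, camera adjusted p = 1.71e-23, 0.000724 with an estimated correlation) differed in this way, these means including undetected probes. Piwil1 was not shown to differ (1.13 ± 1.58, limma adjusted p = 0.611). The rises of Pgk2 were not compared in size, since it was undetected in the 14.5 dpp culture. Axoneme genes (9 of 30) and endothelial genes (7 of 21) changed less or fell more in culture (camera adjusted p = 0.00123 and 0.0189, each 0.821 with an estimated correlation). Sertoli cell genes differed upward in 10 of 24 cases (camera adjusted p = 0.00215, 0.424 with an estimated correlation), with Sox9 at 1.86 ± 0.39 (limma adjusted p = 0.000372) and Acta2 of peritubular cells at 1.30 ± 0.20 (limma adjusted p = 5.43e-06). The Sertoli list did not rise in culture: its mean change was -0.96 in vivo and -0.04 in culture. Acta2 likewise fell in vivo, from 14.60 to 13.23, and stood at 14.35 and 14.27 in culture. Cyp17a1 differed by -3.35 ± 1.24 (limma adjusted p = 0.0318). Adgre1 rose more in culture (limma adjusted p = 0.0045), but it was undetected in the 14.5 dpp culture, so no exact size is given. The median of all genes was 0.24 in this difference, and 0.67 with median centring. The share of upward differences was 54.9%, 78.8% with median centring and 44.4% with the authors' values.

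Lists called in none of the 12 comparisons, besides that of Leydig cells, were lymphocytes (lowest camera adjusted p = 0.52), granulocytes (0.262), adipocytes (0.0704), skeletal muscle (0.0698), heat shock (0.286) and the unfolded protein and amino acid response (0.152), the lowest with an estimated correlation being 0.28 for skeletal muscle and 0.216 for adipocytes. Of the 133 list calls, 132 kept the sign of their mean under the authors' values, median centring and no background correction, and 1, differentiating spermatogonia from culture day 7 to 14, did not. These settings rescale the same arrays for lists already called, so a kept sign is weak support. Most calls were lost with an estimated correlation, and in several comparisons other splits of the same arrays called as many lists.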

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

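A change that differs between culture and in vivo was singled out before the arrays were seen as a result to be looked at again, and 13 values met that rule or concerned unnamed probes. The change from 14.5 to 21.5 dpp differed between culture and in vivo in 3387 genes.

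Several of these differences concerned spermatids. The mean of the elongating spermatid list differed by -4.9438 and that of the round spermatid list by -3.328 (each camera adjusted p = 0.000724 with an estimated correlation). The axoneme list differed by -0.8642, a call lost with an estimated correlation (camera adjusted p = 0.821). Among single genes the fitted differences were -6.7539 for Prm1, -6.5381 for Acrv1 and -5.1223 for Tnp1 (limma adjusted p = 1.64e-13, 3.33e-21 and 4.66e-08). They rest on probes not above background in all but 1 of the 4 groups, Acrv1 having been detected on 1 of 3 arrays of the day 14 culture, so their sizes are not exact. What the arrays give are bounds on the rise in vivo, at least 48.5-fold for Prm1, 68.8-fold for Acrv1 and 20.1-fold for Tnp1. Prm1 and Acrv1 were detected in vivo only at 21.5 dpp, while Tnp1 was also detected in vivo at the other ages except 14.5 dpp, at up to 6.82 ± 1.52. Other genes of the round spermatid list were well detected in the day 14 culture, Acrbp at 10.31 ± 0.68 and Crem at 9.34 ± 0.32. Both were already detected on all arrays at culture day 7, at 7.02 ± 0.13 and 6.63 ± 0.46. In vivo 7 of 29 members of this list rose and 1 fell from 7.5 to 14.5 dpp. These levels alone therefore do not show that round spermatids were present in the culture. Prm1 had a level of 4.58 ± 0.12 in culture and 11.25 ± 1.40 in vivo at 21.5 dpp (n = 3 each).

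Somatic genes differed in both directions. The Sertoli cell list differed by 0.927 and the endothelium list by -0.9116, calls lost with an estimated correlation (camera adjusted p = 0.424 and 0.821). With median centring the endothelium list differed by -0.38. Acta2 of peritubular cells differed by 1.2997, the macrophage gene Adgre1 by 2.323 and the steroidogenic gene Cyp17a1 by -3.3515 (limma adjusted p = 5.43e-06, 0.0045 and 0.0318). Adgre1 was undetected on all arrays of the 14.5 dpp culture, so the size of its difference is not exact. Cyp17a1 rose in vivo from 8.84 ± 2.25 to 12.71 ± 0.14 and stood in culture at 7.08 ± 0.77 and 7.60 ± 0.33 at these ages. The wide spread in vivo at 14.5 dpp bears directly on that difference.

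Of 3741 probes without a single gene name, 551 were higher and 640 lower in culture at 21.5 dpp. They entered no gene or list count, and what they measure was not examined.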

How the results depend on the processing

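The number of called genes changed with the values used. Differences were smaller in the authors' values, where the means of called lists had a median ratio of 0.628 to those reported here. The same 2-fold threshold was therefore stricter there, and the counts are not at like thresholds. With the authors' values 293, 220, 210, 415, 285 and 2105 genes were called for culture against in vivo at 9.5, 11.5, 13.5, 14.5, 16.5 and 21.5 dpp, and 665 and 2080 for 14.5 against 7.5 and 21.5 against 14.5 dpp in vivo. There were 322, 277 and 378 for culture day 2, day 7 and day 14 against day 7, and 1673 for the difference of the step, with 27 genes shared by all 6 ages. Of those, for example, 289 of 293 at 9.5 dpp and 2060 of 2105 at 21.5 dpp were called in the same direction in the normalized values. With the authors' values and all 39 arrays, a setting added later, the counts in the same order were 293, 219, 190, 415, 286, 2104, 665, 2080, 322, 277, 377 and 1678, with 27 at all ages.

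Median centring gave 1297 genes at 13.5 dpp, 1836 at culture day 7, 2408 for day 14 against day 7 and 5292 for the difference. Without background correction there were 578, 480, 436, 807 and 567 genes from 9.5 to 16.5 dpp, 1185 for 14.5 against 7.5 dpp in vivo, 643, 583 and 706 for culture day 2, day 7 and day 14 against day 7, and 52 at all ages. Fitting the compared groups only gave 412 at 9.5 dpp, 532 at 16.5 dpp and 50 at all ages. With no minimum fold the counts were 2844, 2591, 1617, 3676, 2651 and 7559 for the 6 ages, 3920 and 7785 in vivo, 2605, 3046 and 3490 for the culture steps, and 197 at all ages.

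Leaving out single arrays gave between 531 and 829 genes at 13.5 dpp, with 531 without in vivo replicate 2 and 552 without in vivo replicate 3. It moved the 16.5 dpp count to 754 (without in vivo replicate 3) and 1650 (without in vivo replicate 2). With 4 doubted arrays left out the 6 ages gave 895, 900, 930, 1476, 928 and 4531 genes, and with 6 left out 902, 910, 878, 1491, 1425 and 4543. With replicate number as a block, a pairing that the labels do not state, day 14 against day 7 gave 1280 genes in place of 1264. The same block in these 2 groups alone gave 1335.

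Gene lists depended on the correlation assumed between genes. With an estimated correlation camera called 4, 0, 1, 0, 4 and 2 lists at the 6 ages, 2 and 2 in vivo, 5, 0 and 0 for the culture steps and 2 for the difference. The fry test called 25 lists at 21.5 dpp, 17 and 24 in vivo and 18 for the difference. A stricter filter gave 3 lists for the difference. The size of the 133 called list means moved more than their sign: 83 were more than 1.5 times smaller with the authors' values, 19 smaller and 6 larger with median centring, and 4 smaller without background correction. With the authors' values the cytokine list at culture day 2 was 1.40 in place of 3.05 and the elongating spermatid list at 21.5 dpp -2.60 in place of -4.92. With median centring the antigen presentation list at 13.5 dpp was 0.20 in place of 0.51.

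Of 1286 named gene values 454 became weaker with the authors' values, 212 without background correction, 110 with median centring and 107 with the compared groups only, and few changed direction. The value of Thbs2, difference of the 14.5 to 21.5 step, was 1.09 and became -0.0741 with the authors' values, also with all 39 arrays. With no filter the value of Cpa3, culture against in vivo at 9.5 dpp, went from -1.77 to 0.213, that of Cpa3, in vivo 14.5 against 7.5 dpp, from -1.12 to 0.1233, and that of Cpa3, culture day 7 against its start, from -1.27 to 0.1512. Values were normalized before the filter, and each gene was represented by its probe with the highest mean. Without the filter another Cpa3 probe can therefore stand for the gene, but which probe was used was not examined. The cause of the change for Thbs2 was not tested.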

Other observations

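Culture day 14 was set against culture day 2, a comparison not described above and chosen after the results were seen. Lyz2, the lysozyme of macrophages, rose by 7.52 ± 0.89 (limma adjusted p = 2.99e-07, n = 3 per group), and Ldhc of spermatocytes rose by 6.51. The acute phase gene Saa3 fell by 5.08 ± 0.67 (limma adjusted p = 1.41e-06), the chemokines Cxcl9, Cxcl1 and Cxcl10 by 4.93, 4.53 and 4.43, and the interferon-induced Ifit3 by 4.01 ± 0.40. Of the macrophage list 20 of 25 members rose, of the pachytene list 22 of 27, while 21 of 25 interferon, 15 of 19 antigen presentation and 16 of 22 cytokine genes fell. With an estimated correlation the camera adjusted p of these 5 lists was 0.165, 0.165, 0.0601, 0.0998 and 0.0798, and of 17 lists called only wound and matrix remodelling kept its call (11 of 16 fell, 1 rose, 0.0402). In all 1170 genes were higher and 1157 lower at day 14.

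Germ cell genes of the cultures were also compared as a whole with each age in vivo. Over 187 germ cell genes the day 14 culture lay at a root mean square log2 distance of 0.77 ± 0.16 from 14.5 dpp in vivo, 0.78 ± 0.17 from 16.5 dpp and 2.68 ± 0.19 from 21.5 dpp. The 3 arrays were nearest to 14.5, 16.5 and 14.5 dpp.

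For the spermatid deficit, the distance over all germ cell genes was chosen before, and that without spermatid and axoneme genes and the residual permutation after, the result was seen. The smallest gap between the distance to 21.5 dpp and that to the nearest earlier age, 1.577, includes the spermatid genes and so restates their lower level. Over the 108 other germ cell genes the smallest gap was 0.1489, with mean distances of 0.79 ± 0.10 to 14.5, 0.80 ± 0.13 to 16.5 and 1.23 ± 0.18 to 21.5 dpp, while Pgk2 stood at 9.58 ± 0.80 in culture against 6.65 ± 0.65 in vivo at 14.5 dpp, so the stage reached was left open. Relabelling within ages gave 11 of 100 groupings as high as the real 3387 genes, the highest other 4920, and permuting residuals gave 1 of 100, the highest other 1374. For lists relabelling gave 88 of 100, with 5 real and 20 the highest other. Relabelling leaves the culture effects in the data, and labels exchanged at a single age turn them into a difference of changes. Its shares therefore do not test the difference of changes alone.

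For the Sertoli and interstitial progenitor genes at 21.5 dpp, the test of quantile normalization was chosen before and that of dilution after the result was seen. With median centring in place of quantile normalization, Sertoli cell genes stayed higher by 0.9311 (SE 0.0651) relative to the median of each array. The same difference was 1.02 in the normalized values, so the choice between these 2 scalings changed it little. Subtracting the array median removes any shift common to all genes, and both scalings assume a stable bulk of genes. The test therefore cannot decide whether that assumption contributed. The shifts of 6 somatic lists differed by 2.0109 (SE 0.0873) between the highest, interstitial progenitors, and the lowest, Leydig cells. Interstitial progenitor genes were already higher at 14.5 dpp (mean 1.07). The Leydig list was called in no comparison, its mean being -0.91 at 9.5 dpp and -0.14 at 14.5 dpp. At 21.5 dpp its mean was -0.36 but its median 0.06, with 3 of 13 members higher and 3 lower. The gap is thus not a shift of the Leydig list as a whole. The gap therefore cannot decide whether a loss of spermatids raised the somatic shares. The Sertoli list changed by -0.96 in vivo from 14.5 to 21.5 dpp and by -0.04 from culture day 7 to 14.

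For the inflammatory and macrophage genes, the tests of decline and of cell number were chosen after and that of the low-signal array before the result was seen. Cytokine genes differed from day 2 to day 14 by -2.2331 (log2, camera adjusted p = 5.24e-11, 0.0798 with an estimated correlation), which restates that they were highest at day 2 and tests no source of the rise. A change in macrophage number alone would move all members of the list one way, which was not seen. In culture 2 were higher and 14 lower at 9.5 dpp, 3 and 3 at 11.5 dpp, 3 and 2 at 13.5 dpp, 3 and 2 at 14.5 dpp, and 15 and 2 at 21.5 dpp. The arrays measured RNA of whole testes, so a member's level need not come from macrophages alone. The test therefore cannot exclude a change in number. The fall of macrophage genes at 9.5 dpp remained without replicate 2 in vivo, at -0.979 (SE 0.2539), with 9 members lower in place of 14 and a camera adjusted p of 0.0123 in place of 0.000793 (0.701 and 0.557 with an estimated correlation).

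For the arrays labelled replicate 3 of the 11.5 and 16.5 dpp cultures, both tests were chosen after the result was seen, and the quality test was reformulated once because its first form gave no decision. Each array correlated better with the other group, by at least 0.0163, which is consistent with an exchange of the 2. The lower of their detected shares was 40.5% and the lower of their correlations with the best match 0.9847. Neither lay below the lowest of the 16 other cultured arrays (38.0% and 0.9819). That gives no sign of lower quality but cannot exclude it. The labels were not changed.

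Other splits of the same arrays were counted for each comparison, but 10 splits are too few for a share under 0.05. For genes the real split gave 1090, 995, 849, 1414, 1044 and 4497 at the 6 ages against a highest other of 43, 2, 186, 2, 396 and 2. It gave 1795 against 1 and 4521 against 7 in vivo, and 1148, 1093 and 1264 against 1, 3 and 3 for the culture steps, so the real split ranked 1 of 10 each time. For lists the real split gave 13, 11, 8, 15, 16 and 11 against a highest other of 9, 13, 13, 15, 15 and 15 at the 6 ages, 11 and 11 against 13 and 11 in vivo, and 10, 11 and 11 against 10, 9 and 12 for the culture steps. In the same order 1, 6, 5, 3, 1, 7, 4, 2, 3, 1 and 4 of 10 splits reached the real count. The 92 genes at all 6 ages were reached by 1 of 100 groupings, the real one itself, the highest other being 0. A shuffled grouping can hardly give calls in 1 direction at all 6 ages, so this outcome says little.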
